A study of Homo sapiens with 14 samples.

How the data were processed

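Small RNA libraries were made from PANC-1, an established human cell line from a pancreatic ductal carcinoma, grown in serum-containing medium. The cells had been exposed to grape proanthocyanidins (PA, oligomers and polymers of flavan-3-ols) at 20 µg/ml or to the vehicle DMSO. The labels gave 7 groups of 2 libraries each, lettered A and B: DMSO at 0, 3, 12 and 24 h and PA at 3, 12 and 24 h. Per the labels' protocols, total RNA was taken up in Trizol and sequenced in paired ends on a NextSeq 500. The labels named 151 nt and 75 nt reads, without saying which applied to these libraries. The series' design text spoke of a biological replicate, but the labels did not say that A and B came from separate cultures. The p-values therefore measure the spread between these libraries, pooled over all groups of a fit, which may be in part technical.

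The authors deposited a table of read counts, whole numbers per mature miRNA entry and library. They also deposited a TPM table, in which each value was the count divided by 1 fixed total per library and scaled to the TPM unit, with no length correction. That total differed from the column sum of the counts by at most 0.006%. Per the submitters' processing notes, bcl2fastq, Bowtie and edgeR were used and the genome build was GRCh38. Their versions and roles, the annotation release, the rule for reads that map to several places and the use of strand were not given in the sources used here. All 28 value columns matched the title of 1 library, and 0 were left over. The counts covered 2848 entries, of which 2346 carried a human miRNA name and 502 carried only a sequence name and a serial number, such as chr8_19924. Neither the sequence nor the position of these 502 unnamed entries was used here, so what they are stays undescribed.

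Total counts per library ran from 1032391 to 3111014, with a median of 2076388. A CPM value is a count scaled to the library total times its TMM factor. A group with a count of 0 in both libraries was set at a floor of 3 counts over the group, and a fold against it was given as a lower bound. Floors cover counting error only and may understate it, because reads copied by PCR are not independent molecules. SD values and the SE values of the edgeR fit include the spread between libraries. The common biological coefficient of variation was 0.203.

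The choices in this paragraph were made before the data were examined. Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, glmQLFit with robust estimation, TMM scaling) after filterByExpr by group, with a minimum count of 10 and a minimum total of 15. This left 810 entries, 682 named and 128 unnamed. All 14 libraries entered one fit by group, from which PA was compared with DMSO at 3, 12 and 24 h. The same fit gave the test that the PA effect differed between the times and the test of DMSO at 3, 12 and 24 h against DMSO at 0 h. The mean PA effect was fitted with time as an additive factor on the 12 libraries of 3, 12 and 24 h, which kept 808 entries. Adjusted p-values are Benjamini-Hochberg values over the entries tested in a comparison, and an entry passed when its adjusted p was under 0.05. Log2 fold changes are PA over DMSO, with the standard error of the edgeR fit.

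Lists of miRNAs were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between members, where at least 3 members were tested. Adjustment ran over 80 tests, 20 lists in 4 comparisons. The lists were the let-7 and miR-98 family, the miR-17-92 and paralogous clusters, the miR-200, miR-29, miR-30, miR-15/16 and miR-181 families, the miR-130, miR-301 and miR-454 family (the miR-130 family), and the miR-23/27/24 clusters, the miR-183, miR-96 and miR-182 cluster (the miR-183 cluster) and the miR-221 and miR-222 cluster (the miR-221 cluster). Further lists held miR-99/100 with miR-125, p53-responsive miRNAs, miRNAs induced by NF-kB and inflammation, miRNAs reported high in pancreatic cancer, miRNAs reported low or growth-suppressive in it, the imprinted 14q32 cluster and the primate cluster of chromosome 19. A list of entries whose sequence lies in tRNA, rRNA, U2 or snoRNA served as a sign of RNA quality. Markers of fibroblast and endothelial cells, red blood cells, haematopoietic cells, muscle, liver and neurons, and acinar and islet cells stood for other sources of RNA. Lipid miRNAs studied with proanthocyanidins in liver made the last list. The lipid list and 4 of the 5 marker lists had fewer than 3 tested members and were described by summed CPM.

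Entries were named by a fixed rule: the 10 largest rises and the 10 largest falls that passed and whose libraries did not overlap between the groups, plus the 5 most abundant that passed. For the mean over the times the rule asked instead for the same direction in at least 5 of 6 same-letter pairs. Where fewer than 10 passed, the entries with the smallest p filled the number up to 10. For the difference between times the 10 smallest adjusted p were taken, and for DMSO the fold of 24 h over 0 h. In each list the 4 most abundant tested members and any that passed were eligible. The miRNAs miR-21-5p, let-7a-5p, miR-34a-5p, miR-200c-3p, miR-210-3p, miR-221-3p and miR-155-5p and the 5 most abundant miRNAs were followed in each comparison. Other miRNAs named beside these were chosen after their values were seen.

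Alternatives fixed in advance were DESeq2 size factors or total counts in place of TMM, no filter, and a minimum mean CPM of 10. They also included leaving out the RNA quality list, the replicate letter as a block, edgeR without robust estimation, and DESeq2 1.42.0. The others were limma-trend on log2(TPM + 1), only the libraries of the groups compared, the mean effect taken from the 14-library fit, camera with an estimated correlation, fry, and leaving out each library in turn. A library left alone in its group by the last of these was assumed to vary like the other groups. The filter was rerun with each library left out and kept 896 to 968 entries in the fit by group, against 810 with all 14. Counts of passing entries in these fits therefore also reflect another set of tested entries. Chosen after seeing the data were PA against the mean of the other DMSO times, leaving out the 12 h libraries, thinning each library to the smallest total, named miRNAs only, and 1 entry kept of each set with identical counts. The first of these compares groups that differ in time as well as in treatment, so it does not measure the PA effect alone.

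The tests were checked on simulated counts drawn from the library means and totals, with 200 entries changed. At 24 h, over 773 tested entries, 40.6% of 2-fold and 75.8% of 4-fold changes were recovered, and 0.7% of the unchanged entries passed. For the mean over the times, over 763 entries, 70.2% and 94.6% were recovered. For the DMSO time course, over 764 entries, 34.7% and 73.7% were recovered. For the difference between times, over 773 entries, changes at 24 h were recovered in 13.5% and 58.9%. A miR-30 list planted with 2-fold changes at 24 h had an adjusted p of 0.000629. The simulated entries varied independently of each other, with the same spread in all groups. These rates therefore check the procedure under its own assumptions and are not error rates of the real data.

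Coordinates of hairpins are from the GENCODE v29 annotation of GRCh38, matched by miRNA gene name, since the deposited tables held no positions. Some named miRNAs had identical counts in all libraries, among them miR-103a-3p with miR-103b, and miR-423-5p with miR-3184-3p from the opposite strand of one hairpin. Reads of such entries cannot be assigned to one of them, and their values are uncertain. Tables were written with Python 3.11.15 and figures were drawn with matplotlib 3.10.9.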

Results

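The series measured miRNAs in PANC-1 cells at 3, 12 and 24 h of exposure to grape PA, with DMSO at the same times and at 0 h as the controls, and asked how PA changed miRNA expression over time. Total counts were 1550026 and 1131473 (DMSO 0 h, A and B), 2762869 and 1781112 (DMSO 3 h), 1710798 and 1032391 (DMSO 12 h), and 2302554 and 2230573 (DMSO 24 h). They were 2420626 and 3111014 (PA 3 h), 1922203 and 2534939 (PA 12 h), and 2816062 and 1236935 (PA 24 h). The 5 most abundant miRNAs, miR-21-5p, miR-100-5p, miR-27a-3p, miR-29a-3p and miR-22-3p, took 47.2% of all counts, those of unnamed entries included. The 10 most abundant entries took 61.4% to 64.8% of a library, and the unnamed entries took 1.65% to 3.17%. Spearman correlations between A and B ran from 0.925 for DMSO 12 h to 0.976, and the counts of each pair differed by more than sampling noise (chi-square over degrees of freedom 14.3 to 83.4). This ratio was 14.3 and 26.4 for DMSO and PA at 3 h, and 83.4 and 65.1 at 12 h. The fit used a single estimate of spread per entry for all groups. A p-value thus does not rest on the spread of the groups compared alone. On the first principal component (27.6% of the variance) every DMSO library lay between -7.65 and -0.48. PA A and B lay at 0.71 and 0.76 at 3 h, 2.52 and 3.55 at 12 h, and 8.31 and 9.57 at 24 h. On the second principal component (22.6% of the variance) DMSO 12 h A and B lay at 5.85 and 10.2, and the other 12 libraries between -4.63 and 5.81.

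At 3 h of PA, 2 entries were higher than with DMSO and 0 were lower. The unnamed entry chr8_19924 rose from 60.9 ± 38.1 to 385 ± 107 CPM (SD, n = 2 each), a log2 fold change of 2.63 ± 0.34 (SE; edgeR adjusted p = 0.000914). The low-abundance miR-7704 rose from 8.07 ± 4.79 to 72.0 ± 33.4 CPM, a log2 fold change of 3.07 ± 0.52 (adjusted p = 0.0118). Its hairpin lies at chromosome 2, 176188843 to 176188901, plus strand, within an exon of HOXD1 on the same strand and an exon of HAGLR on the opposite strand, so its reads cannot be told from fragments of these transcripts. The well-known cancer miRNAs did not pass: log2 fold changes were -0.12 for miR-21-5p, -0.11 for let-7a-5p, 0.23 for miR-155-5p, 0.14 for miR-34a-5p, 0.15 for miR-210-3p, -0.09 for miR-221-3p and -1.24 ± 0.55 for miR-200c-3p, a repressor of ZEB1. Others with the smallest p, none passing, were miR-6069 (0 counts in both PA libraries against 4.12 CPM in DMSO, adjusted p = 0.521), miR-431-3p (log2 fold change 1.70, adjusted p = 0.809), miR-873-3p (1.14), chr9_21367 (2.28), chr2_5914 (-0.88) and chr19_35739 (0.73).

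Of the 810 entries, 14 had an unadjusted p under 0.05 at 3 h, where chance alone gives 40.5. The spread was pooled with groups whose pairs differed more, such as those at 12 h, so p-values at 3 h may run high. The few passing entries therefore do not show that PA had little effect at 3 h. No member of any list passed, and the smallest adjusted p of a list was 0.293, for both the fibroblast and endothelial list and the miR-17-92 clusters. With only the 4 libraries of the groups compared, chr8_19924 no longer passed (adjusted p = 0.202). miR-7704 no longer passed without DMSO 3 h A (adjusted p = 0.0589), DMSO 3 h B (0.201), DMSO 12 h A (0.187), DMSO 12 h B (0.171) or PA 3 h A (0.268).

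**Figure D1:**
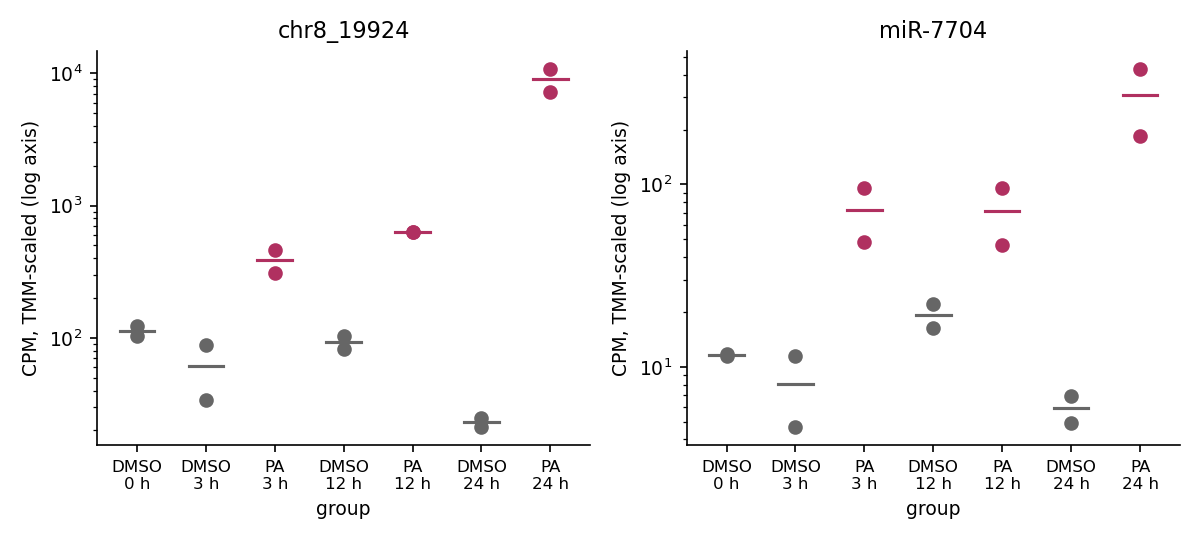
CPM (log axis) of chr8_19924 and miR-7704 in each of the 14 libraries by time, with DMSO in grey, PA in red, points for libraries and bars for group means. The PA 24 h mean of chr8_19924 is 9007 CPM against 23.1 CPM in DMSO 24 h, and that of miR-7704 is 308 CPM against 5.93 CPM.

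At 12 h, 51 entries were higher and 39 lower with PA than with DMSO. miR-27a-3p, the third most abundant miRNA, rose from 41400.4 ± 5636 to 79459 ± 3029.7 CPM (SD, n = 2 each; log2 fold change 0.94 ± 0.14, edgeR adjusted p = 0.000471). The hypoxia-induced miR-210-3p rose from 929.9 ± 156 to 2391 ± 164 CPM (1.36 ± 0.19, adjusted p = 0.000353). miR-96-5p rose from 1289 ± 495 to 6771 ± 1351 CPM (2.39 ± 0.31, adjusted p = 0.000284). In the other direction miR-146a-5p, an NF-kB-induced repressor of TRAF6 and IRAK1, fell from 59150.4 ± 1913 to 38544 ± 1940.02 CPM (-0.62 ± 0.14, adjusted p = 0.0113), and miR-146b-5p fell from 574 ± 91 to 217 ± 53.3 CPM (-1.40 ± 0.20, adjusted p = 0.000471).

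The DMSO 12 h libraries stood apart from the other DMSO times in these miRNAs. In DMSO at 0, 3 and 24 h, miR-27a-3p had 67628, 73157 and 68015 CPM and miR-210-3p had 1753, 1418 and 2163 CPM. Of the 90 entries that passed, 72 (80%) had a DMSO 12 h mean farther than the PA 12 h mean from the mean of the other DMSO times. The median distances were 0.789 for DMSO 12 h and 0.255 for PA 12 h (log2 CPM). Set against the mean of the other DMSO times, a comparison chosen after seeing the data, PA at 12 h had 5 passing entries, 3 higher and 2 lower. Of the 90, only chr8_19924 and miR-7704 were among these 5. The groups of this comparison also differ in time in culture.

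**Figure D2:**
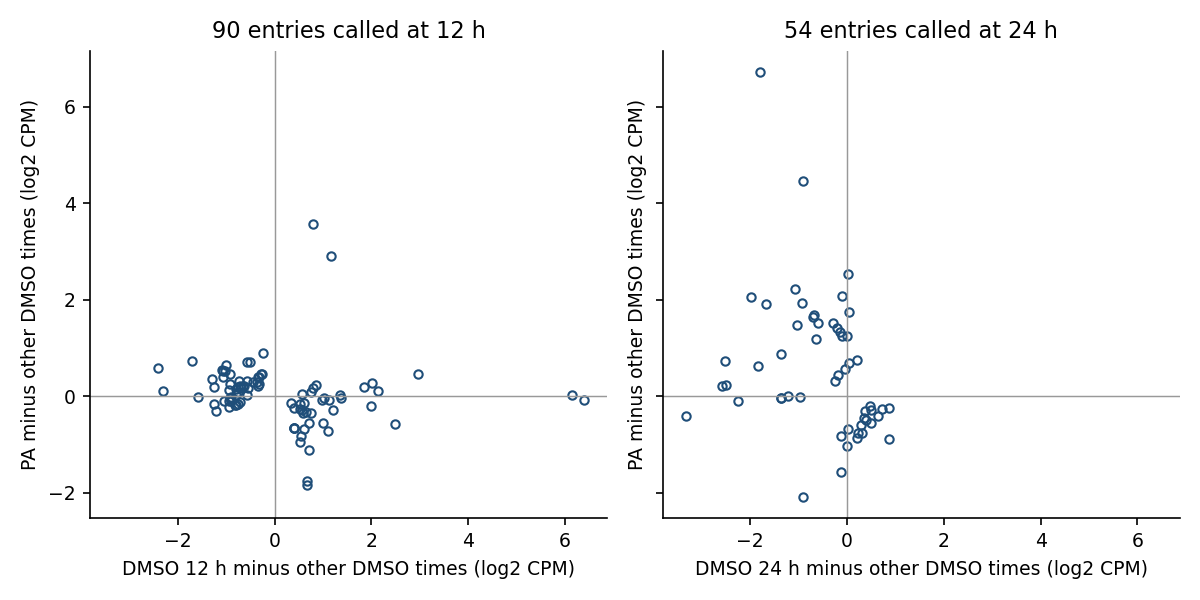
Entries that passed at 12 h and at 24 h, with the DMSO mean minus the mean of the other DMSO times on the x axis and the PA mean minus the same mean on the y axis (log2 CPM), 1 point per entry. At 12 h 80% of the 90 points lie farther from 0 on the x axis than on the y axis, and at 24 h 31.5% of the 54 do.

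The other large rises at 12 h were miR-135a-5p (from 1.88 to 20.4 CPM, log2 fold change 3.27 ± 0.52), chr8_19924 (2.78 ± 0.34), miR-153-3p (2.07), miR-33a-3p (1.72), miR-19a-3p (1.68), miR-33a-5p (1.63 ± 0.26), miR-188-3p (1.56), miR-19b-3p (1.55) and miR-377-3p (1.46). The 2 arms of MIR33A come from an intron of SREBF2 (chromosome 22, 41900944 to 41901012, plus strand), and miR-33a-5p represses ABCA1. miR-34a-5p, a direct p53 target, rose by 1.12 ± 0.25 (adjusted p = 0.0108) but did not pass without DMSO 12 h B (adjusted p = 0.084). Large falls were those of chr7_18301 (92.4 CPM in DMSO and 0 in both PA libraries, at least 138-fold lower), chr14_29384 (238.8 to 2.26 CPM, -6.70; 1.94 to 3.08 CPM in DMSO at the other times), miR-5684 (at least 6.56-fold lower), miR-3960 (-3.89), miR-4695-3p (-3.68), chr17_33942 (-2.47), miR-1268b (-2.29), miR-1268a (-2.13), miR-3142 (-2.09) and miR-6715b-3p (-1.85). Relative to the mean of the other DMSO times (log2 CPM), chr7_18301 lay at 6.39 in DMSO 12 h and at -0.08 in PA 12 h. miR-99a-5p (-1.78 ± 0.27, adjusted p = 0.00069), let-7c-5p (-1.60) and miR-370-3p (-1.27) also fell. Among the abundant miRNAs, miR-23a-3p (0.87) rose and let-7i-5p (-0.51) and miR-221-3p, a repressor of CDKN1B, fell (-0.83, adjusted p = 0.0468). The log2 fold changes of miR-21-5p (-0.02), let-7a-5p (-0.10), miR-29a-3p (0.15), miR-22-3p (-0.33), miR-200c-3p (-0.01) and miR-155-5p (-0.24) did not pass.

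By list, all 3 members of the miR-183 cluster (miR-183, miR-96 and miR-182, one polycistron) rose at 12 h, the same 3 adjusted over the list alone: miR-96-5p, miR-183-5p (1.25) and miR-182-5p (0.57, adjusted p = 0.0422). miR-182-5p passed in only 8 of the 14 alternative settings other than leaving out 1 library. With each library left out in turn its value ran from 0.49 to 0.69, but it did not pass in most of these fits. The list passed (median log2 fold change 1.25, camera adjusted p = 0.000394), with adjusted p = 0.731 with an estimated correlation. Against the other DMSO times its median was 0.74 (adjusted p = 0.0178). Of the 5 members of the miR-23/27/24 clusters, 3 rose (4 adjusted over the list alone): miR-27a-3p, miR-23a-3p and miR-27b-3p (0.57), while miR-24-3p (0.14) did not pass. This list also passed (median 0.57, adjusted p = 0.00628; adjusted p = 0.731 with an estimated correlation), but not against the other DMSO times (median 0.19, adjusted p = 0.602). Of 14 growth-suppressive miRNAs, 3 rose (miR-34a-5p, miR-96-5p, miR-15a-5p) and miR-146a-5p fell, or 5 and 1 adjusted over the list alone. That list passed (median 0.74, or 0.68 with members absent from one group at their bound; adjusted p = 0.0152, and adjusted p = 0.852 with an estimated correlation). It did not pass without DMSO 12 h B (adjusted p = 0.197) or against the other DMSO times (0.564).

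In the remaining lists at 12 h, few members passed and no list did. Of 14 miRNAs reported high in pancreatic cancer, 4 rose (miR-27a-3p, miR-23a-3p, miR-210-3p, miR-301a-3p) and miR-221-3p fell, likewise 4 and 1 adjusted over the list alone (list adjusted p = 0.243). Of 12 NF-kB and inflammation-induced miRNAs, miR-9-5p rose (0.67) and miR-146a-5p, miR-146b-5p and miR-221-3p fell, or 2 and 4 adjusted over the list alone (list adjusted p = 0.426). Among 9 let-7 members let-7c-5p and let-7i-5p fell (3 adjusted over the list alone, list adjusted p = 0.426), and among 9 p53-responsive miRNAs miR-34a-5p and miR-107 (0.73) rose (2 adjusted over the list alone, 0.293). In the miR-15/16 family miR-15a-5p and miR-424-5p rose of 7 (3 adjusted over the list alone, 0.0638). In the miR-17-92 clusters miR-19a-3p and miR-19b-3p rose of 11 (3 adjusted over the list alone, 0.698), and in the miR-130 family miR-130b-3p and miR-301a-3p rose of 4 (2 adjusted over the list alone, 0.293). miR-29b-3p rose of 3 miR-29 members (1 adjusted over the list alone, 0.426). In the miR-30 family miR-30e-5p rose and miR-30d-5p fell of 5 (2 and 1 adjusted over the list alone, 0.861).

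One member fell in the miR-221 cluster list (miR-221-3p of 4; 1 adjusted over the list alone; list adjusted p = 0.571) and one in the miR-99/100 and miR-125 list (miR-99a-5p of 5; 1 adjusted over the list alone; 0.304). In the 14q32 cluster miR-377-3p and miR-494-3p rose and miR-370-3p and miR-369-3p fell of 36 (2 and 2 adjusted over the list alone; 0.779). No member passed in the miR-200 (list adjusted p = 0.7), miR-181 (0.939), chromosome 19 (0.601) or fibroblast and endothelial (0.16) lists. The last had a median log2 fold change of 1.30, or 0.76 with absent members at their bound. Of the 13 entries that overlap other small RNAs, the tRNA-derived miR-4454 rose (1.10, adjusted p = 0.0498; 0 adjusted over the list alone; list adjusted p = 0.966). Their summed CPM was 4770.1 ± 1771 in DMSO 12 h and 9058 ± 3267 in PA 12 h. Summed CPM in DMSO 12 h and PA 12 h was 573 ± 41.8 and 466 ± 70.5 for red blood cell miRNAs, 5.5 and 4.0 for haematopoietic, 4.3 and 4.1 for muscle, liver and neuron, and 9.7 and 8.3 for acinar and islet miRNAs. It was 66.2 ± 10.1 and 202 ± 26.3 for the lipid miRNAs. In DMSO at 0, 3 and 24 h the lipid sum was 135, 148 and 149 CPM, so DMSO 12 h was low here too.

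In all, 90 of 810 entries passed at 12 h and 213 had an unadjusted p under 0.05. The count was 45 without DMSO 12 h B, 42 without PA 12 h A, 34 without PA 12 h B, and 33 with only the 4 libraries of the groups compared. TMM gave 56.7% of the passing entries higher, total counts 50.6% (44 of 87) and DESeq2 size factors 48.2% (41 of 85), while the directions given for the families above did not turn. Of the 47 entries named at 12 h that passed, 16 passed with each library left out in turn, among them miR-27a-3p, miR-23a-3p, miR-210-3p, miR-96-5p, miR-183-5p, miR-146b-5p and miR-99a-5p. miR-146a-5p did not pass without PA 12 h A (0.119) or PA 12 h B (0.0744), miR-27b-3p without DMSO 12 h B (0.158) or PA 12 h B (0.0919), and miR-221-3p in 13 of the 14 fits, with 0.602 without DMSO 12 h B. With total counts the median log2 fold change of all entries was -0.11 at 12 h and -0.19 at 24 h, against -0.06 and -0.01 with TMM. miR-7704 (1.87 ± 0.49, adjusted p = 0.0272) did not pass without DMSO 12 h A (0.12), DMSO 12 h B (0.187) or PA 12 h B (0.225).

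At 24 h, 35 entries were higher and 19 lower with PA. Of the 11 tested members of the miR-17-92 clusters, MYC- and E2F-regulated and linked to proliferation, 6 fell, though as a list they did not pass with an estimated correlation (adjusted p = 0.731). Among them miR-20a-5p fell from 5166 to 2874 CPM (log2 fold change -0.85 ± 0.21, edgeR adjusted p = 0.0229), miR-17-5p from 2549 to 1461 CPM (-0.80, adjusted p = 0.0158) and miR-18a-5p from 330.3 to 179 CPM (-0.88 ± 0.18, adjusted p = 0.0091). miR-7-5p, which represses EGFR, fell from 163 to 79.8 CPM (-1.01 ± 0.22, adjusted p = 0.0116). Among the most abundant miRNAs, miR-100-5p rose from 93134 ± 983 to 137446 ± 12263 CPM (0.56 ± 0.15, adjusted p = 0.0321; n = 2 each) and miR-27a-3p from 68015 ± 1529.7 to 99262 ± 8110.4 CPM (0.55 ± 0.14, adjusted p = 0.0246). The largest change was that of chr8_19924, from 23.1 ± 2.67 to 9007 ± 2552 CPM (8.60 ± 0.43, adjusted p = 2.82e-09), which made up 0.638% and 1.04% of the counts of PA 24 h A and B.

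Set against the mean of the other DMSO times, a comparison chosen after seeing the data, PA at 24 h had 69 passing entries, 50 higher and 19 lower, with 29 of the 54 among them. chr8_19924 (6.70), miR-7704 (4.61), chr13_28163 (1.95), miR-27a-3p (0.75, adjusted p = 0.000512), miR-99b-5p (0.56), miR-92a-3p (-0.68, adjusted p = 0.00836) and miR-3529-3p (-0.72) passed. miR-20a-5p (-0.57, adjusted p = 0.0572), miR-17-5p (-0.45, 0.0949), miR-18a-5p (-0.49, 0.064), miR-7-5p (-0.53, 0.0973), miR-100-5p (0.31, 0.132), miR-562 (0.85, 0.529) and miR-372-5p (0.23, 0.906) kept their direction and did not pass, and miR-99a-5p (-0.06) and miR-6750-5p (-0.48) turned. This comparison sets PA at 24 h against DMSO at 0, 3 and 12 h, so it mixes PA with time in culture. In DMSO alone 106 entries changed over time, so the 69 entries are not a count of PA effects. These other times include DMSO 12 h, which stood apart, and whose 41400.4 CPM lowered the reference for miR-27a-3p.

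The other large rises at 24 h were mostly of scarce entries. miR-7704 rose from 5.93 ± 1.42 to 308 ± 174 CPM (5.68 ± 0.55, adjusted p = 9.59e-06) and chr13_28163 from 45.2 ± 13.7 to 327 ± 29.5 CPM (2.85 ± 0.26, adjusted p = 4.06e-06). miR-562 and miR-372-5p had 0 counts in both DMSO 24 h libraries and were at least 13.3-fold and at least 9.82-fold higher with PA, and had 9.79 and 5.05 CPM in DMSO at 0 h. miR-6069 (5.02), chr6_15979 (4.96), miR-4709-5p (4.53), miR-6750-5p (1.48 to 18.0 CPM, 3.50 ± 0.69) and chr17_33942 (2.90) also rose. The falls were smaller: miR-4521 (-1.53), miR-579-3p (-1.48), miR-6715b-3p (-1.27), miR-376b-3p (-1.15), miR-196a-3p (-1.11), miR-191-3p (-1.10), miR-4455 (-1.06), miR-3529-3p (2509 to 1229 CPM, -1.03 ± 0.20, adjusted p = 0.00617), miR-7-5p and miR-154-3p (-0.98). MIR3529 (chromosome 15, 88611847 to 88611924, minus strand) lies opposite MIR7-2 (88611825 to 88611934, plus strand). The use of strand was not given, but miR-423-5p and miR-3184-3p, from opposite strands of one hairpin, had identical counts. Strand thus did not separate the reads of that pair. The counts of miR-3529-3p and miR-7-5p differed, but the origin of their reads is uncertain, and their falls may not be separate ones.

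By list at 24 h, 6 of 11 tested miR-17-92 members fell, 7 adjusted over the list alone: miR-17-5p, miR-18a-5p, miR-20a-5p, miR-106a-5p (-0.97), miR-92a-3p (-0.69) and miR-93-5p (-0.68). All 11 had negative log2 fold changes (median -0.73), and the list passed (camera adjusted p = 1.29e-05), with adjusted p = 0.731 with an estimated correlation. Against the other DMSO times the median was -0.45 (adjusted p = 0.0178). Summed CPM of the list was 24973 ± 298.4 in DMSO 24 h and 15707 ± 4199 in PA 24 h, with 18676 in PA 24 h A and 12738 in PA 24 h B. MIR17, MIR18A and MIR20A lie in MIR17HG (chromosome 13, 91350605 to 91351135, plus strand), MIR106A on chromosome X (134170198 to 134170278, minus strand) and MIR93 in an intron of MCM7 (chromosome 7, 100093768 to 100093847, minus strand).

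In the imprinted 14q32 cluster miR-376a-3p (-0.77) and miR-376b-3p fell, 3 adjusted over the list alone, and 28 of 36 members had negative values (median -0.25). The list passed (adjusted p = 0.00826; adjusted p = 0.731 with an estimated correlation), but not without PA 24 h B (0.167), and its median was 0.03 against the other DMSO times. Of the 5 members of the miR-99/100 and miR-125 list, 3 rose, likewise 3 adjusted over the list alone: miR-100-5p, miR-99a-5p (0.96 ± 0.27, adjusted p = 0.044) and miR-99b-5p (0.60 ± 0.16, adjusted p = 0.035). The miR-99 family represses mTOR. The list did not pass (median 0.56, adjusted p = 0.134). Of the miR-23/27/24 clusters miR-27a-3p rose (3 adjusted over the list alone; list adjusted p = 0.211), and its other arm miR-27a-5p rose as well (0.66 ± 0.16, adjusted p = 0.0161). MIR27A lies at chromosome 19, 13836440 to 13836517, minus strand, and MIR100 at chromosome 11, 122152229 to 122152308, minus strand, in an intron of MIR100HG.

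Of the other lists, miR-27a-3p and miR-100-5p rose among the miRNAs reported high in pancreatic cancer (3 adjusted over the list alone; list adjusted p = 0.81), and miR-221-5p (0.63) in the miR-221 cluster (1 adjusted over the list alone; 0.939). miR-4521 fell among the entries that overlap other small RNAs (1 adjusted over the list alone; 0.914), whose summed CPM was 7856 ± 1180.5 in DMSO 24 h and 9930.4 ± 1458 in PA 24 h. No member passed over all entries in the let-7 (list adjusted p = 0.861), miR-200 (0.939), p53 (0.939), NF-kB (0.779), growth-suppressive (0.861), miR-29 (0.698), miR-30 (0.81), miR-15/16 (0.293), miR-183 cluster (0.357), miR-181 (0.698), miR-130 family (0.861), chromosome 19 (0.861) and fibroblast and endothelial (0.7) lists. Adjusted over the list alone, 1 member of the miR-30 and 1 of the miR-183 cluster list passed. The log2 fold changes of miR-21-5p (-0.07), let-7a-5p (-0.19), miR-29a-3p (-0.08), miR-22-3p (0.08), miR-200c-3p (-0.39), miR-34a-5p (0.40), miR-210-3p (0.19), miR-221-3p (-0.03) and miR-155-5p (-1.04, adjusted p = 0.188) did not pass. Summed CPM in DMSO 24 h and PA 24 h was 402 ± 11.9 and 539 ± 42.3 for red blood cell, 1.7 and 3.3 for haematopoietic, 5.9 and 9.3 for muscle, liver and neuron, 4.2 and 8.8 for acinar and islet, and 149 and 202 for lipid miRNAs.

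In all, 54 of 810 entries passed at 24 h and 169 had an unadjusted p under 0.05. Without DMSO 24 h A 12 passed, without DMSO 24 h B 13 and without PA 24 h B 31, and without either DMSO 24 h library no passing entry was lower. Of the 32 entries named at 24 h that passed, chr8_19924, miR-7704 and chr13_28163 passed with each library left out in turn. The other 29 did not pass without DMSO 24 h A (adjusted p from 0.0541 for miR-3529-3p to 0.329 for miR-376a-3p), nor did 28 without DMSO 24 h B, among them miR-20a-5p (0.122 and 0.108), miR-17-5p (0.122 and 0.109), miR-7-5p (0.0687 and 0.0951), miR-100-5p (0.197 and 0.163) and miR-27a-3p (0.122 and 0.163). Without PA 24 h B the adjusted p was 0.242 for miR-20a-5p and 0.218 for miR-17-5p, and without PA 24 h A 0.107 for miR-100-5p and 0.0667 for miR-27a-3p. miR-27a-5p, run apart from these, did not pass without DMSO 24 h A (0.17), DMSO 24 h B (0.124) or PA 24 h A (0.0724). TMM gave 64.8% of the passing entries higher and total counts gave 38.7% (29 of 75), where miR-27a-3p (0.36, adjusted p = 0.0749), miR-100-5p (0.38, 0.0946), miR-99a-5p (0.78, 0.0946) and miR-99b-5p (0.41, 0.111) kept their direction and did not pass.

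**Figure D3:**
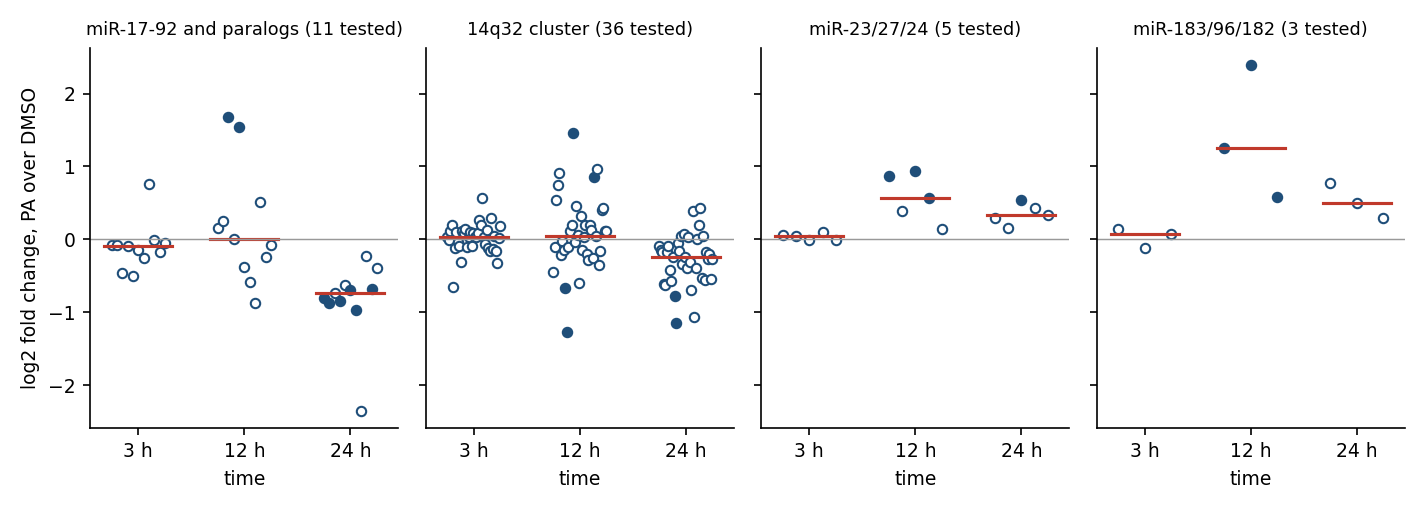
Log2 fold change of PA over DMSO at 3, 12 and 24 h for the tested members of 4 lists, 1 point per miRNA, filled where the adjusted p was under 0.05, with a red line at the median. The miR-183 cluster median at 12 h is 1.25 and the miR-17-92 median at 24 h is -0.73.

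Over 3, 12 and 24 h together, 6 PA against 6 DMSO libraries, 0 of 808 entries passed with edgeR, although 118 had an unadjusted p under 0.05. The 10 entries with the smallest p each had an adjusted p of 0.154. These had log2 fold changes of 3.49 ± 0.62 (miR-7704), 1.58 (chr14_29090), 1.29 (chr12_26635), 0.85 (chr19_35739), 0.72 ± 0.18 (miR-183-5p), 0.56 (miR-30d-3p), 0.49 ± 0.13 (miR-27a-3p), -0.74 (miR-301a-5p), -0.75 (miR-625-3p) and -1.08 ± 0.26 (miR-6715b-3p). The values of miR-21-5p (-0.07), let-7a-5p (-0.13), miR-34a-5p (0.54), miR-200c-3p (-0.54), miR-210-3p (0.56), miR-221-3p (-0.32) and miR-155-5p (-0.34) did not pass either. DESeq2 passed 21 and limma-trend 2, and the mean of the 3 effects in the 14-library edgeR fit, which takes effects that differ by time out of the spread, passed 51. Without PA 12 h A 2 passed, and 1 each without DMSO 3 h A and without PA 24 h B.

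For this mean effect 3 lists passed, with no member passing over all entries. The miR-23/27/24 clusters were higher (median 0.36, adjusted p = 0.00664; 3 higher adjusted over the list alone), as was the miR-183 cluster (0.72, 0.00873; 3 higher). The miR-17-92 clusters were lower (-0.24, 0.0203; 3 lower adjusted over the list alone). With an estimated correlation the adjusted p was 0.852, 0.852 and 0.927. The first 2 did not pass without the 12 h libraries, where DMSO stood apart (adjusted p = 0.125 and 0.324). The third did not pass without DMSO 24 h A (0.202), DMSO 24 h B (0.142), PA 24 h A (0.0544) or PA 24 h B (0.471). Of all 8 list results that passed at the preset correlation, 0 passed with an estimated one (smallest adjusted p = 0.731). fry, which asks whether members move one way without comparing them with other entries, passed 9.

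List median, mean and test differed in sign in 17 of the 80 tests, none of which passed. At 3 h these were the miR-200, NF-kB, miR-29, miR-30, miR-221 cluster and other small RNA lists, and at 12 h the miR-30 list. At 24 h they were the let-7, miR-200, p53, high in pancreatic cancer, miR-221 cluster and other small RNA lists. For the mean they were the p53, high in pancreatic cancer, miR-99/100 and miR-125, and fibroblast and endothelial lists.

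The PA effect differed between 3, 12 and 24 h for 48 entries. chr8_19924 had the smallest adjusted p (2.63, 2.78 and 8.60, adjusted p = 3.32e-06). chr13_28163 had values of 0.02, 0.94 and 2.85 (adjusted p = 0.000951). The value of miR-99a-5p was negative at 12 h and positive at 24 h (-0.04, -1.78 and 0.96, adjusted p = 0.00305), as were those of miR-6750-5p (-0.97, -1.78 and 3.50), chr17_33942 (-1.34, -2.47 and 2.90), chr1_2271 (0.46, -0.78 and 2.59), and chr4_10821 and KI270790.1_41873, which had identical counts (0.03, -1.04 and 1.38). Against the other DMSO times these signs did not all hold: miR-99a-5p was 0.20 at 12 h and -0.06 at 24 h, chr17_33942 was 0.63 at 12 h, and miR-6750-5p was 0.43 at 12 h and -0.48 at 24 h. miR-377-3p was higher at 12 h than at the other times (-0.11, 1.46 and -0.16, adjusted p = 0.00384). chr14_29384 was lower with PA than with DMSO at 12 h, but not against the other DMSO times (-0.04, edgeR adjusted p = 0.984). miR-96-5p (adjusted p = 0.00538), miR-146b-5p (0.00746), miR-210-3p (0.0128) and miR-27a-3p (0.0193) also differed.

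Across entries, which are not independent, the PA effects at 3 and 12 h had a Spearman correlation of 0.17, those at 3 and 24 h 0.058, and those at 12 and 24 h -0.039. The 12 and 24 h comparisons had 11 passing entries in common, 5 in the same direction and 6 in opposite ones, where independent lists give 6 (Fisher's exact test p = 0.0284, two-sided). They share no library but come from one fit with a single estimate of spread per entry, so they are not independent. The 11 also count chr4_10821 and KI270790.1_41873 separately, although their counts were identical. This p-value therefore cannot show a shared effect. The count of 48 was 25 without DMSO 24 h A, 26 without DMSO 24 h B, 26 without PA 12 h A, 28 without PA 12 h B, 82 without DMSO 12 h A and 87 without PA 24 h A. Without the 12 h libraries, where DMSO stood apart, it was 10. miR-210-3p did not pass without PA 12 h A (0.0679), nor miR-27a-3p in 6 of the 14 fits that left out a library (0.0946 without PA 3 h A).

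In DMSO alone, 106 entries changed over 0, 3, 12 and 24 h. miR-146a-5p changed from 25640.4 ± 62 CPM at 0 h to 36038, 59150.4 and 43746 CPM at 3, 12 and 24 h (edgeR adjusted p = 0.000415; log2 of 24 h over 0 h 0.77). Other entries that passed and were higher at 24 h were miR-380-3p (1.74), miR-33b-3p (1.15), miR-19b-3p (1.06), miR-376a-3p (0.95), miR-370-3p (0.94), miR-7-5p (0.86), miR-135a-5p (0.84), miR-409-3p (0.77) and miR-665 (0.77). Lower at 24 h were miR-6750-5p (-3.89), chr1_2271 (-2.57), miR-4802-3p (-2.56), chr16_32004 (-2.44), miR-4310 (-2.29), chr8_19924 (-2.28) and miR-4485 (-2.01). miR-562, miR-372-5p and miR-4634 had 9.79, 5.05 and 3.19 CPM at 0 h and 0 counts in both DMSO 24 h libraries.

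Abundant miRNAs that passed over the DMSO times included let-7i-5p (0.34 at 24 h over 0 h), let-7g-5p (0.20), miR-23a-3p and miR-27a-3p, which lay at -0.71 at 12 h over 0 h. miR-210-3p also passed (adjusted p = 0.00316). Of the 810 entries, 241 had an unadjusted p under 0.05. The count was 67 without DMSO 24 h A and also without DMSO 24 h B, and 32 without the 12 h libraries, 28 of which were among the 106. Of the 25 entries named here, 10 passed with each library left out in turn, among them miR-146a-5p, miR-210-3p, miR-370-3p, miR-409-3p, miR-135a-5p and miR-6750-5p. let-7g-5p did not pass in 12 of the 14 fits (0.152 without DMSO 0 h B), miR-27a-3p without DMSO 12 h B (0.0525), and miR-562 without DMSO 24 h A (0.0633) or DMSO 24 h B (0.0555).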

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

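Of the tests below, those of depth by thinning, of the departure of the DMSO 12 h libraries and of RNA in the PA preparation were chosen only after the result was seen, as was the use of the planned total-count and leave-one-out fits to test scaling and a single library. The PA effect differed between 3, 12 and 24 h for 48 of 810 entries by a test of that difference (edgeR). The adjusted p was 3.32e-06 for chr8_19924, 0.000951 for chr13_28163 and 0.00305 for miR-99a-5p. It was 0.00384 for each of chr1_2271, chr14_29384, chr17_33942, chr4_10821, KI270790.1_41873, miR-377-3p and miR-6750-5p. Among the miRNAs followed in each comparison, miR-210-3p (0.0128) and miR-27a-3p (0.0193) differed as well.

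For the 90 entries that passed at 12 h, lower depth was argued against as the whole cause: 74 entries passed after every library was thinned to the smallest total, 63 of the 90 among them, while the other 27 no longer passed with 625 entries tested. A departure of the DMSO 12 h libraries is consistent with most of the pattern: 80% of the 90 entries had a DMSO 12 h mean farther than the PA 12 h mean from the other DMSO times. Cells of other types in the DMSO 12 h cultures cannot be told apart from this: the highest log2 ratio over the other DMSO libraries was 0.9 (SE 0.20), for acinar and islet miRNAs at 10.2 and 9.1 CPM against 4.7, and 2 more of the 5 marker sums were under 10 CPM. Of the 2 larger sums, that of red blood cells was higher (543.8 and 602.9 against 368 CPM, 0.64, SE 0.10), and that of fibroblast and endothelial cells was lower (825.9 and 968.5 against 1427.6 CPM, -0.67, SE 0.12), which goes against added cells of these last types. An effect of PA at 12 h stays open, as does any difference in how the DMSO 12 h cultures were handled, which the labels do not describe.

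The rise of chr8_19924 at 24 h was weighed next. Scaling was argued against by a log2 fold change of 8.43 with total counts, and a single library by a lowest value of 8.31 over the fits that left out each library in turn. The lowest value over all settings was 6.70, against the other DMSO times, and DMSO 24 h itself lay at -2.28 over 0 h. Small RNA brought in with the PA preparation cannot be told apart from a response of the cells, because each PA library had both and no sequence of the entry was used here. Its level in PA libraries was higher at 24 h than at 3 h by 4.55 on the log2 scale, which uptake over time or induction by PA could both give, so both stay open as hypotheses.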

How the results depend on the processing

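Chosen only after the results were seen were the settings of PA against the other DMSO times, without the 12 h libraries, thinned libraries, named miRNAs only and identical entries once. Of the values of named entries that passed, 1383 kept direction and side of the threshold over the settings other than leaving out 1 library, 186 kept only the direction and 11 reversed. With each library left out in turn the numbers were 1277, 375 and 0. For lists that passed they were 89, 16 and 1, and 106, 6 and 0. miR-27a-5p and 6 entries of the chromosome X cluster were run apart from these counts.

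The 0 entries of the mean effect became 16 with no filter, 1 with the mean CPM filter, 1 without robust estimation, 21 with DESeq2, 2 with limma-trend, 51 in the group fit and 2 after thinning. The 8 list results became 0 with an estimated correlation, 19 with no filter and 4 without the 12 h libraries, a setting that removes the 12 h comparison, where 3 of the 8 lay. With only the libraries of the groups compared, 1 entry passed at 3 h, 33 at 12 h and 39 at 24 h. Named miRNAs only, with fewer entries tested, gave 1 entry at 3 h and 22 for the difference between times. Without the 12 h libraries the latter was 10 and the DMSO time course 32. Against the other DMSO times 5 entries passed at 12 h. Except as said, the cause was not tested.

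Against the mean of the other DMSO times, log2 fold changes at 12 h reversed for chr17_33942 (0.63), let-7i-5p (0.042), miR-1268a (0.20), miR-130b-3p (-0.19), miR-146a-5p (0.17), miR-29b-3p (-0.16), miR-30e-5p (-0.11), miR-362-3p (-0.02), miR-424-5p (-0.05) and miR-99a-5p (0.20), and at 24 h for miR-6750-5p (-0.48), miR-99a-5p (-0.058) and the 14q32 median (0.026). Further passing entries turned as well, among them chr13_28163 (-0.31) and miR-6750-5p (0.43) at 12 h and chr16_32004 (-0.09) at 24 h. The change of control is the construction of this setting. No other setting run reversed a value that had passed, among the lists and the entries named by the fixed rule. Among all passing entries, those not named in the text included, the sign of DMSO 24 h over 0 h was kept least without DMSO 0 h A (67 of the 76 still passing), and that of the PA effect at 24 h over 3 h least without PA 3 h A (30 of 35).

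With each library left out in turn, entries passing ranged from 1 to 2 at 3 h, 34 to 107 at 12 h, 12 to 71 at 24 h, 0 to 2 for the mean, 25 to 87 for the difference between times and 67 to 136 for DMSO, and list results from 8 to 10. Because the filter was rerun, these fits tested 896 to 968 entries at 3, 12 and 24 h instead of 810. The ranges therefore do not show the influence of 1 library alone. With the replicate letter as a block the counts were 2, 77, 50, 0, 42 and 103, and 8 lists. The letters shared only a number: the 21 correlations between same-letter deviations ran from -0.165 to 0.114 (median -0.017), with 1 over 0.1. Over both libraries, 3 counts corresponded to 0.63 CPM in DMSO 24 h and 0.67 CPM in PA 12 h, where entries that passed had 0 counts. In the smallest library alone, DMSO 12 h B, they corresponded to 2.73 CPM, so a level below this rested on fewer than 3 counts there.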

Other observations

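The tests of hairpin clusters, of depth by thinning, of the share of low-abundance entries and of the fall of the DMSO 24 h libraries were chosen only after the results were seen. Hairpins were grouped into 15 clusters (same strand, gaps of at most 10 kb in GENCODE v29, at least 4 tested entries with 1 hairpin gene each), and Fisher's exact test asked whether entries that passed were overrepresented (two-sided, Benjamini-Hochberg over 60 tests). In a cluster on chromosome X (50003148 to 50014683, plus strand, within CLCN5), a group on no list, 7 of 13 entries rose at 12 h (adjusted p = 0.000284, median log2 fold change 0.72, 10 of 13 positive). They were miR-362-3p (1.54), miR-188-3p (1.56), miR-532-3p (0.96), miR-500a-5p (0.84), miR-660-5p (0.81), miR-500a-3p (0.74) and miR-362-5p (0.72). miR-532-5p, from the same hairpin as miR-532-3p, had 0.13 (edgeR adjusted p = 0.632). At 24 h 0 of the 13 passed in edgeR. The test counts the arms of a hairpin and the neighbours on a transcript as independent, which they are not. The cluster passed with each library left out in turn (highest adjusted p = 0.0399, without DMSO 12 h A), but not after thinning (4 entries, 0.103) or with only the libraries of the groups compared (2 entries).

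The DMSO 12 h libraries stood apart in this cluster too, and against the other DMSO times 0 of the 13 passed. miR-362-3p had 200.3, 207, 66.5 ± 16.9 and 189 CPM in DMSO at 0, 3, 12 and 24 h and 196 ± 2.89 CPM in PA at 12 h (SD, n = 2). The other clusters that passed were the miR-183 cluster at 12 h (chromosome 7, 129770383 to 129775014, 3 of 4 entries higher, adjusted p = 0.0217) and MIR17HG at 24 h (chromosome 13, 91350605 to 91351135, 3 of 7 lower, adjusted p = 0.0104). The first did not pass in 9 of the 14 fits that left out a library (adjusted p from 0.101 to 0.535). The second did not pass without DMSO 24 h A, DMSO 24 h B or PA 24 h B, where 0 of 7 were lower, or without DMSO 3 h B (1 of 7, 0.866). Neither passed against the other DMSO times.

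The 35 entries higher with PA at 24 h were weighed as the third pattern. That rises outnumbered falls depended on scaling. With total counts 29 of the 35 still passed as higher, but 46 entries passed as lower. With limma-trend on log2(TPM + 1) 24 were higher and 45 lower. The share of low-abundance entries was 0.527% and 0.666% in PA 24 h A and B, and 0.661% and 0.616% in DMSO 24 h A and B. Its log2 ratio of -0.11 (SE 0.18) showed no larger share with PA, but overlapping pairs of libraries cannot exclude one. Lower depth was argued against by 32 of the 35 passing after thinning, among 56 in all. A fall of the DMSO 24 h libraries was argued against as the whole cause, since the PA 24 h mean lay within the range of the 8 DMSO libraries for only 31.4% of these entries, 11 of 35. For those 11 a fall in DMSO could account for the difference. An effect of PA on the others stays open as a hypothesis, found and tested on the same libraries.

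For the mean effect over 3, 12 and 24 h, 100 splits of the 12 libraries were drawn without regard to time, the real one included. All 100 gave at least the real 0 entries (highest other 45), as any split must, so this count decides nothing about chance. For list results 22 of the 100 gave at least the real 3 (highest other 7), so chance could not be excluded. The splits with 45 and 33 entries set PA against DMSO within 12 h alone and within 24 h alone, so the splits held part of the treatment contrast itself.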
